A study of Mus musculus with 2 samples.

How the data were processed

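Sorted CD45+ cells from mouse tumours were profiled with 10x 5′ gene expression chemistry in 2 libraries, 1 labelled WT and 1 labelled Ythdf2 cKO. The deposited values are counts of UMIs per gene and cell barcode, as made by the authors with Cell Ranger against mm10. Their processing notes name Cell Ranger 5.0.1 and Seurat 4.0.4, whereas the matrix header names cellranger 5.0.0, and the counting options and annotation release are not given in the sources used here. Both files held 31053 genes, of which 30934 have their identifier in GENCODE vM21, the source of the GRCm38 coordinates. The libraries held 14404 and 11398 barcodes, with 128952491 and 121321782 UMIs, and no barcode was under 500 UMIs.

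Barcodes with under 200 genes (174 and 274) or over 10% mitochondrial UMIs (2221 and 1528) were left out, which kept 12179 and 9865. Doublets were scored per library with Scrublet as built into scanpy. Its automatic threshold failed, calling 4154 barcodes (34.1%) in the library labelled WT and 0 in the library labelled cKO. The rate planned beforehand, 0.8% per 1000 cells, was used instead, and the 1187 and 779 highest scores (9.74% and 7.89%) were removed. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1, without batch integration. Ythdf2, list genes that are not markers, mitochondrial and ribosomal protein genes, immunoglobulin and T cell receptor variable segments, Xist and Y-linked genes were left out of the variable genes. T and NK cells were clustered again on their own.

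A cluster took the name of the fixed marker set with the highest mean expression, scaled per marker to its highest cluster, when at least 3 of its markers were each found in 25% of the cells. It stayed unnamed when at least 2 of Cd3e, Csf1r and Cd79a were each found in 60% of its cells, when under 50% of the cells of an immune cluster had Ptprc, or when another set had more markers among its 10 leading genes. T cell clusters needed Cd3 genes in 50% of cells on average and subtype genes in 50% (Cd4 in 30%). NK clusters needed Cd3 genes in under 30% and NK genes in 40%. T cell clusters without a subtype were called other T cells, as were those in which another set had more leading markers. T or NK clusters also stayed unnamed when C1qa was found in 50% or Csf1r in 60% of the cells. Names end in "-like" because no protein was measured.

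UMIs were summed per class and library, and the 10 classes with at least 100 cells in each library were compared as log2 ratios of CPM with a pseudocount of 1 CPM. The median log2 ratio of all genes lay near 0 in each class, so no further scaling was applied. For 26 gene lists and 22 marker sets fixed beforehand, members of at least 10 CPM in either library were used, with 3 or more needed. Each median was placed among 10000 random lists matched over 20 expression bins, and its interval came from 1000 Poisson redraws. A member counted as higher or lower at 1.5-fold. Genes were named by a rule written before the data were examined for macrophage-like and CD8 T-like cells. It took the 12 genes with the largest log2 ratio on each side among those with at least 50 CPM in a library and 100 UMIs over both. Genes under 0.2 of their level in another class of the same library, mitochondrial, ribosomal protein, haemoglobin and antigen receptor segment genes, unnamed gene models and sex-linked genes were left out. Members of lists were named as examples. Using that rule for monocyte-like cells, choosing which lists to describe and naming the Klra genes, Rpl29 and other single genes came after values were seen. For shares of cells with a UMI, cells were thinned without replacement to the lower of the 2 libraries' percentile 20 depths, and cells below it were left out. With 1 library per group, no test between groups was made.

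The method was tested on simulated data drawn as Poisson counts from the pooled profile of a class at the UMI totals of the 2 libraries. These data held no variation between cells, clusters or libraries beyond counting error, so the intervals were checked for that error only. In macrophage-like cells (7814 genes) and CD8 T-like cells (7494 genes), all 50 genes changed by each of 4 fold sizes were recovered within 0.5 log2, and 95.9% of ratio intervals held the truth in both. A simulated 2-fold list of 15 genes reached percentile 100 in each class, over 7942 and 7692 genes. Of 200 unchanged lists, 1.5% and 5.5% lay beyond the outer percentiles 2.5 and 97.5. Thinning simulated cells of 2 depths brought the ratio of genes per cell, deep over shallow, from 2.07 to 1.00 in macrophage-like cells (31053 genes).

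Alternatives planned beforehand were 500 genes per cell, 5% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, marker gates per cell, median-of-ratios size factors, equal weight per cell, thinned cells, a pseudocount of 10 CPM and no filter on low values. Classes under 100 cells in a library entered the shares, and otherwise only the Ythdf2 and Lyz2 values of 2 of them are given. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.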

Results

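Leukocytes carrying CD45, the pan-leukocyte surface protein, were sorted from mouse tumours and profiled by droplet-based single-cell RNA sequencing from the 5′ end of transcripts. There was 1 library from tumours of mice labelled WT and 1 from mice labelled Ythdf2 cKO, a conditional knockout of the m6A reader Ythdf2. The question named by the series is what this reader does in tumour-associated macrophages and in tumour immunity. The library labelled WT held 14404 barcodes with 128952491 UMIs and a median of 4760 UMIs per barcode. The library labelled cKO held 11398 barcodes with 121321782 UMIs and a median of 7404. After filtering, 10992 and 9086 cells were kept, with median depths of 5128 and 7997.5 UMIs. With 1 library per label there was no replicate and no test, so each difference describes these 2 libraries. Brackets give exact 95% intervals, Poisson for CPM (the UMIs of a gene scaled to a common total) and Clopper-Pearson for shares of cells, which cover counting error only. Intervals of list medians come from Poisson redraws of the counts and cover the same error.

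Ythdf2, a cytoplasmic reader that promotes decay of m6A-modified transcripts, was measured first because it checks the labels. Its RNA (ENSMUSG00000040025, GRCm38 chromosome 4, 132184912 to 132212303, minus strand) was higher, not lower, in the myeloid classes of the library labelled cKO. Monocyte-like cells held 52.2 CPM (48.6 to 56.1) in the library labelled WT and 415 CPM (408 to 422) in the library labelled cKO, a ratio of 7.95 (7.38 to 8.56). The corresponding ratios were 5.04 (4.76 to 5.33) in macrophage-like cells, 6.999 (5.20 to 9.60) in neutrophil-like cells and 2.44 (2.08 to 2.88) in cDC2-like cells. Lymphoid classes differed little, with ratios of 1.08 (0.930 to 1.248) in NK-like, 1.13 (0.930 to 1.39) in CD8 T-like and 1.04 (0.673 to 1.61) in B-like cells. Lyz2, the lysozyme gene of myeloid cells, was lower in the library labelled cKO, at 9479 and 4501 CPM in monocyte-like cells and 4178 and 1871 CPM in macrophage-like cells. The Ythdf2 paralogues Ythdf1 and Ythdf3 stood at 36.2 and 41.2 CPM in macrophage-like cells of the library labelled WT and at 44.8 and 45.5 CPM in the library labelled cKO. The m6A machinery list had medians of 0.02 (log2; -0.04 to 0.12) in macrophage-like and -0.01 (-0.12 to 0.06) in monocyte-like cells. Ythdf2 thus went against the label, and 5′ reads can lie outside the deleted part, so its level did not check the deletion. Every direction given here, from the library labelled WT to the library labelled cKO, carries that reservation. Alternatives were run for Ythdf2 in macrophage-, monocyte- and CD8 T-like cells, and among these the CD8 T-like log2 ratio of 0.17 moved to 0.60 in cells thinned to 1 depth and to 1.01 in cells taken by marker gates.

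**Figure D1:**
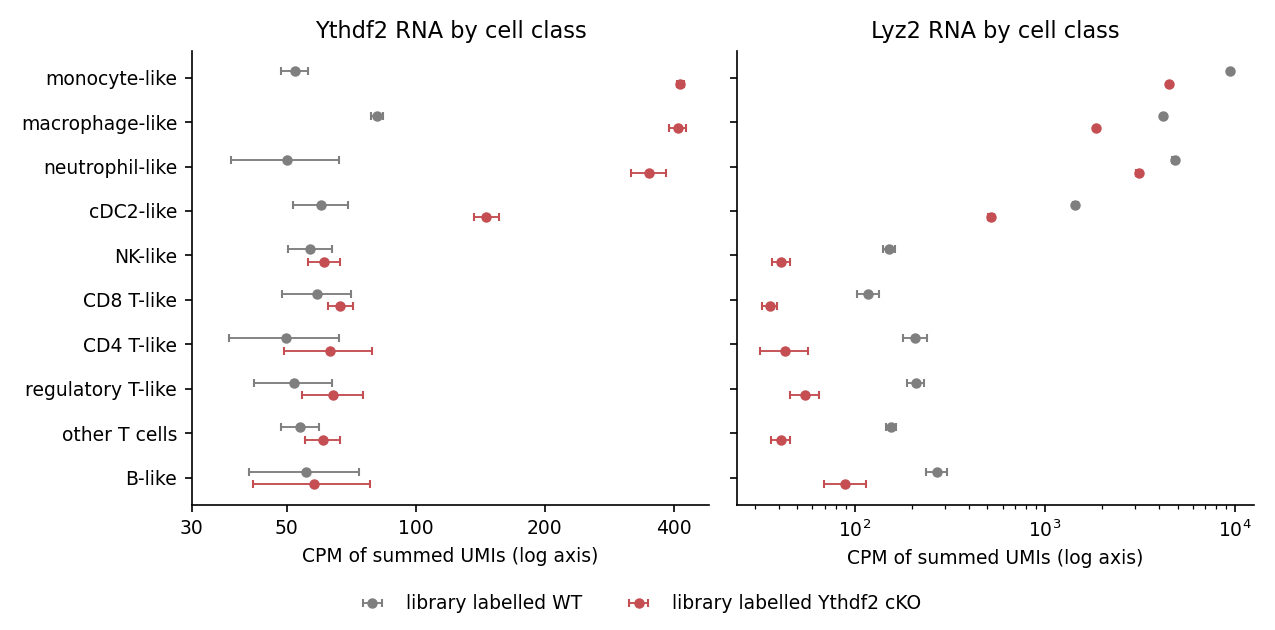
Ythdf2 (left) and Lyz2 (right) RNA per cell class as CPM of summed UMIs on log axes, with a point per library (grey, labelled WT; red, labelled cKO) and exact 95% Poisson intervals for counting error. Ythdf2 in monocyte-like cells stands at 52.2 CPM in the library labelled WT and 415 CPM in the library labelled cKO, against 56.8 and 61.1 CPM in NK-like cells.

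Macrophage-like cells, named from C1qa, C1qb, C1qc, Apoe and other fixed markers, made up 20.3% (19.5 to 21.1) of the library labelled WT and 2.05% (1.77 to 2.36) of the library labelled cKO. That share was 9.91-fold (8.53 to 11.6) lower, with 2230 and 186 cells. Monocyte-like cells were 17.3% (16.6 to 18.0) and 26.2% (25.3 to 27.1), so that these 2 classes together held 37.6% and 28.2% of cells. There were 0.854 monocyte-like cells per macrophage-like cell in the library labelled WT and 12.8 in the library labelled cKO. All 3 macrophage-like clusters were smaller in the library labelled cKO. Cluster C5 held 1239 and 86 cells, the cycling cluster C14 569 and 29, and cluster C17, led by Mmp12 and Arg1, 422 and 71. Melanocytic cells with Pmel and Dct, which the sort should exclude, were 1.52% (1.30 to 1.77) and 0.242% (0.152 to 0.366). A low-Ptprc cluster with C1qa and Pf4, C11, stayed unnamed and held 4.08% and 2.48% of cells. Marker gates per cell moved the log2 ratio of the macrophage-like share from -3.31 to -1.36. The monocyte-like log2 ratio of 0.60 became 0.34 with at most 5% mitochondrial UMIs and -0.0048 at a Leiden resolution of 2.0.

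CD8 T-like cells were 2.25% (1.98 to 2.54) of the library labelled WT and 15.7% (14.995 to 16.5) of the library labelled cKO, 7.0-fold (6.12 to 8.05) higher. Regulatory T-like cells with Foxp3 were 3.32% (2.99 to 3.67) and 2.94% (2.60 to 3.31). The number of CD8 T-like cells per regulatory T-like cell was 0.677 (0.573 to 0.798) and 5.36 (4.70 to 6.13). Marker gates gave 1119 CD8 T-like and 595 regulatory T-like cells in the library labelled WT, and 2057 and 377 in the library labelled cKO. The libraries thus differed less in this ratio under marker gates. CD4 T-like cells were 2.73% and 2.21%, gamma delta T-like cells with Trdc and Il17a 1.75% and 0.770%, and other T cells 16.2% and 10.97%. Other T cells included cluster T5, with 392 and 191 cells and Cd8a UMIs in 48.5% of them. T5 made up 3.57% and 2.10% of cells, so counting it as CD8 T-like would make the 7.0-fold ratio smaller. NK-like cells were 11.6% (10.998 to 12.2) and 14.4% (13.7 to 15.2), or 12.7% and 19.7% with the unnamed cluster T4, which passed the NK rule. cDC2-like cells were higher in the library labelled cKO, 2.82% and 4.24%. Plasmacytoid DC-like cells (2.46% and 1.00%), neutrophil-like cells (2.40% and 1.21%) and B-like cells (3.28% and 2.18%) were lower. Clusters without a name held 10.6% and 14.6%. Marker gates moved the CD8 T-like log2 ratio from 2.81 to 1.15, and the NK-like log2 ratio of 0.32 became 0.53 to 0.71 under 7 alternatives, each given with the dependence on processing. The regulatory T-like log2 ratio of -0.18 (-0.41 to 0.06) became -0.38 (-0.57 to -0.20) under marker gates and -0.29 with at most 5% mitochondrial UMIs, and the CD4 T-like value of -0.30 became -0.57 under marker gates and -0.55 at a Leiden resolution of 2.0. At most 5% mitochondrial UMIs moved the B-like log2 ratio from -0.59 to -1.51, and marker gates moved it to -0.96.

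**Figure D2:**
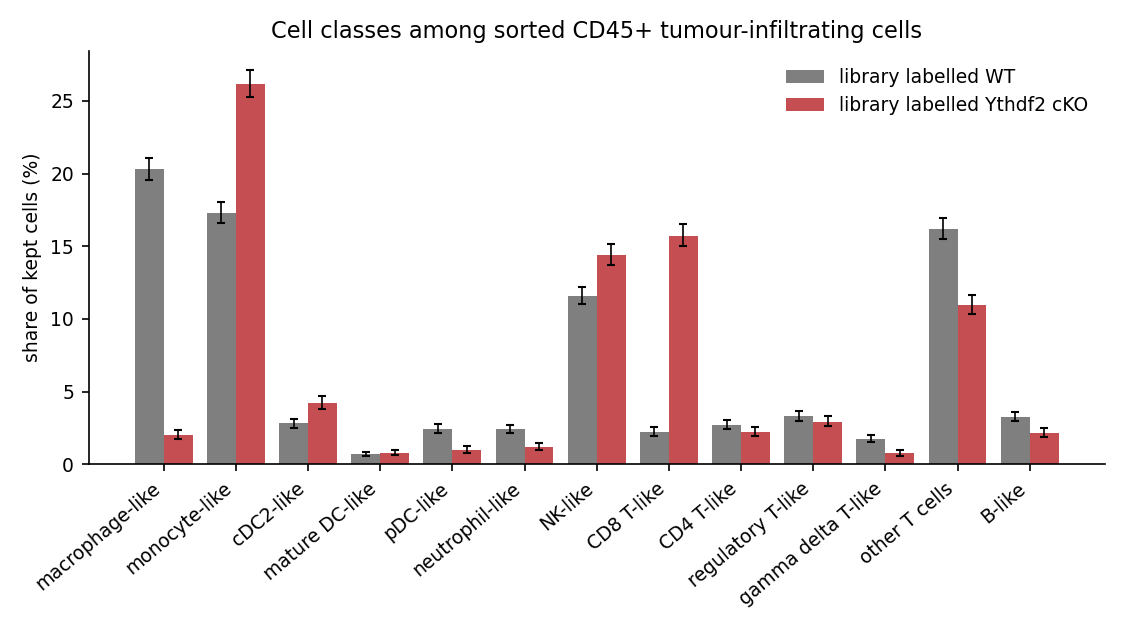
Share of kept cells (%) in each class for the library labelled WT (grey) and the library labelled cKO (red), with exact 95% binomial intervals for counting error. Macrophage-like cells make up 20.3% and 2.05%, and CD8 T-like cells 2.25% and 15.7%.

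In macrophage-like cells of the library labelled cKO, genes induced by interferon gamma were higher together. Of 19 measured members of the interferon gamma response list, 17 were at least 1.5-fold higher and 0 lower, a size and not a test. Their median log2 ratio was 1.20 (1.10 to 1.30), at percentile 100 of 10000 random lists matched on expression. Cxcl9, a chemokine for activated T cells, was 136 CPM (133 to 140) in the library labelled WT and 482 CPM (462 to 503) in the library labelled cKO. Gbp2, an interferon-induced GTPase, was 60.0 and 208 CPM, Serpina3g 29.4 and 94.5 CPM, and Iigp1 35.9 and 103 CPM. The type I interferon list had a median of 0.96 (0.86 to 1.06), with 16 of 19 members higher, among them Isg15 at 46.1 and 152 CPM. MHC class II genes, which present antigen to CD4 T cells, had a median of 1.00 (0.95 to 1.05), with 6 of 8 higher, including H2-Aa at 663 and 1385 CPM and Cd74 at 1801 and 3827 CPM. For MHC class I and antigen processing the median was 0.46 (0.41 to 0.50), with 6 of 19 higher, H2-T23 being 170 and 325 CPM. The inflammatory list had a median of 0.62 (0.49 to 0.69) with 6 of 12 higher. These included Ccl5 at 339 and 824 CPM and the prostaglandin synthase Ptgs2 at 141 and 280 CPM. Ccl5 was far higher in CD8 T-like cells, at 3089.5 CPM in the library labelled WT and 10458 CPM in the library labelled cKO. Cd3e UMIs were found in 34.4% and 33.3% of macrophage-like cells. RNA of T cells could thus account for the Ccl5 values in macrophage-like cells, which was not tested. The checkpoint ligand Cd274 was 76.6 and 160 CPM.

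Other genes named by the size rule in macrophage-like cells were Inhba, a subunit of activin A, at 18.8 and 111 CPM, and AA467197, at 22.1 and 105 CPM. Slamf8, Il18bp, Ifi205 and the complement gene C3 had log2 ratios from 1.53 to 1.76. Lower in the library labelled cKO were Fcrls, at 155 and 52.2 CPM, the chemokine Pf4, at 2059 and 718 CPM, the growth factor Igf1, at 130 and 56.4 CPM, and the mannose receptor Mrc1, at 536 and 252 CPM. Gas6, which bridges apoptotic cells to phagocytes, was 112 and 54.8 CPM. Gdf3, Wwp1, Dusp7, Cela1, Igfbp4 and Pmp22 had log2 ratios from -1.35 to -0.94. Of 12 measured alternatively activated macrophage genes, 4 were higher, including Chil3 at 39.4 and 125 CPM, and 1, Mrc1, was lower, with a median of 0.24 (0.14 to 0.32). Cell cycle genes had a median of -0.37 (-0.49 to -0.31), with Mki67 at 208 and 133 CPM, and oxidative phosphorylation -0.18 (-0.22 to -0.15). Lipid-associated macrophage genes (-0.01) and phagocytosis and lysosome genes (0.03) stood near 0. Monocyte markers were also higher in this class, with a median of 0.91 (0.75 to 0.98) and Ly6c2 at 215 and 437 CPM, while melanocytic markers were lower (-0.78). Inhba and Ptgs2 led monocyte-like cluster C13, and Chil3 and C3 led monocyte-like cluster C6. In the library labelled cKO, another class held 222 CPM of Inhba and 276 CPM of C3. Monocyte-like cells there held 904 CPM of Cxcl9 and 878 CPM of Gbp2. RNA of monocytes, or monocytes named macrophage-like, could thus account for part of these values, which was not tested. Cytotoxic genes of T and NK cells were higher too (0.84), with Gzma at 59.6 and 236 CPM. Fcrls and Pf4 were among the genes leading cluster C5, Arg1 among those leading C17 and Mki67 among those leading C14, so their values may in part restate cluster sizes. With clusters weighted as in the library labelled WT, 3 named genes moved by over 1.5 times, Arg1, Inhba and Ptgs2. Fcrls and Pf4 were not among them.

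Marker gates moved the macrophage-like medians to 1.86 for interferon gamma, 1.70 for type I interferon, 1.5 for MHC class II and 0.91 for MHC class I, and moved 22 named genes by over 1.5 times, among them Pf4 from -1.52 to -3.12 and Lyz2 from -1.16 to -0.53. The inflammatory median ranged from 0.30 with clusters weighted as in the library labelled WT to 1.24 under marker gates, and that weighting turned the alternatively activated list to -0.16, with Arg1 (main 0.73) at -0.16, and moved Inhba from 2.496 to 1.30 and Ptgs2 from 0.99 to 0.35. The cell cycle median became -0.08 under that weighting, -0.64 with every cell weighted equally and -2.13 under marker gates. Ptgs2 also moved to 0.57 with at least 500 genes per cell, and thinned cells moved Ifit3 from 1.13 to 0.75 and Dusp7 from -1.29 to -0.82.

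Monocyte-like cells, 1904 and 2379 in number, also had more interferon-induced RNA in the library labelled cKO, the library whose Ythdf2 level went against its label. The interferon gamma response list had a median of 1.06 (1.02 to 1.15), with 18 of 19 members higher. Cxcl9 was 321 CPM (312 to 331) and 904 CPM (893 to 914), Gbp2 324 and 878 CPM, and Irgm1, an immunity-related GTPase, 108 and 292 CPM. The type I interferon median was 0.85 (0.83 to 0.92), with Ifit3 at 65.2 and 252 CPM and Isg15 at 91.6 and 349 CPM. T cell attracting chemokines had a median of 0.83 (0.78 to 0.86), and Cxcl10 was 971 and 1979 CPM. Chemokines for monocytes and neutrophils were lower, with a median of -0.43 (-0.44 to -0.42), Cxcl1 being 203 and 121 CPM and Ccl6 829 and 545 CPM. MHC class II genes, higher in macrophage-like cells, had a median of -0.12 (-0.14 to -0.11) here. Mrc1 was 115 and 35.9 CPM and Eps8, an actin regulator, 188 and 49.1 CPM. The alternatively activated list stood at -0.21 (-0.28 to -0.11). Cytotoxic genes were higher (1.38), with Gzma at 14.1 and 74.1 CPM, and melanocytic markers were lower (-2.36). Cxcl9 and Gbp2 also led monocyte-like cluster C2, which was formed without them. The alternatively activated median moved to -0.0552 with at least 500 genes per cell, -0.12 in thinned cells or with clusters weighted as in the library labelled WT, and -0.13 with median-of-ratios factors.

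Cxcl9 UMIs were found in more cells at matched depth. In macrophage-like cells thinned to 8150 UMIs, 21.1% (19.2 to 23.04) had Cxcl9 in the library labelled WT and 41.6% (33.6 to 49.96) in the library labelled cKO, with 446 and 37 shallower cells left out. Unthinned shares of cells with Cxcl9 were 27.4% and 48.4%, at median depths of 16951 and 19824 UMIs. Monocyte-like cells thinned to 5196 UMIs had Cxcl9 in 18.7% (16.7 to 20.7) and 37.6% (35.6 to 39.7), leaving out 381 and 144 cells. Unthinned, these were 20.5% and 44.4%, at median depths of 7074 and 12473 UMIs. B-like cells, which should lack Cxcl9, had it in 2.43% and 4.64% when thinned to 1897 UMIs, from median depths of 2244.5 and 3496.

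**Figure D3:**
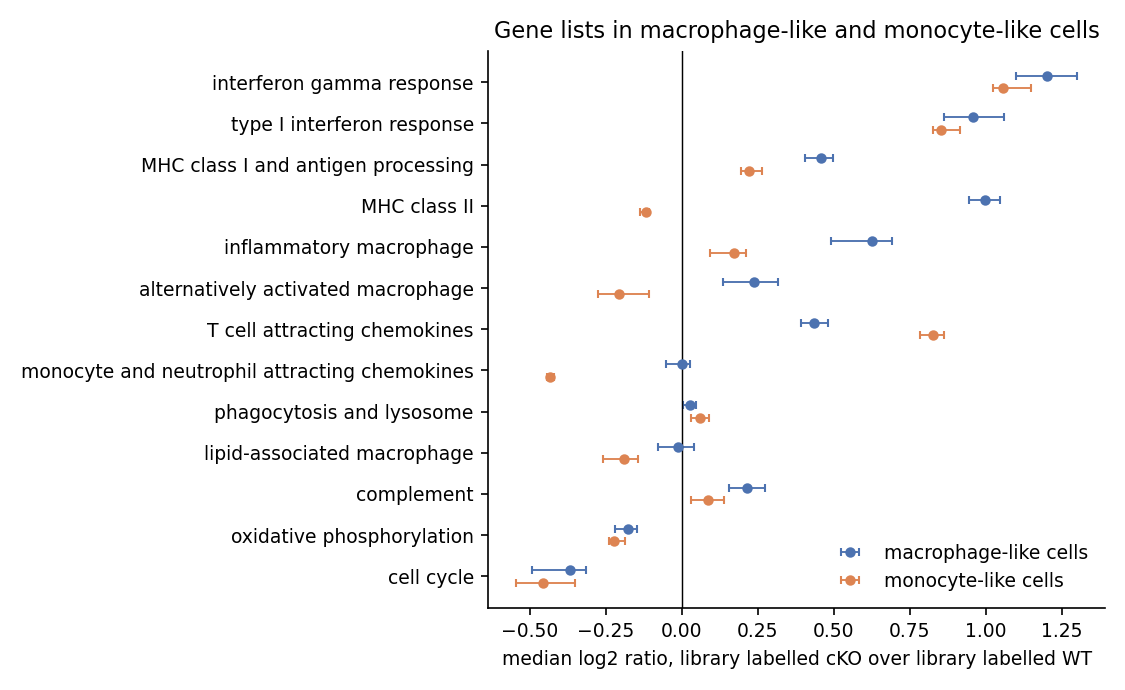
Median log2 ratio, library labelled cKO over library labelled WT, of each gene list in macrophage-like (blue) and monocyte-like (orange) cells, with intervals from Poisson redraws of the counts. The interferon gamma list stands at 1.20 and 1.06, whereas MHC class II stands at 1.00 in macrophage-like and -0.12 in monocyte-like cells.

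CD8 T-like cells of the library labelled cKO held more RNA of cytotoxic effectors. The granule proteases Gzma and Gzmb were 489 CPM (459 to 521) and 480 CPM (449 to 511) in the library labelled WT. In the library labelled cKO they were 1998 CPM (1974 to 2023) and 1710 CPM (1687 to 1732). Prf1, the pore former perforin, was 257 and 429 CPM. Of 15 cytotoxic effector genes 12 were at least 1.5-fold higher and 1 lower, with a median of 0.74 (0.68 to 1.04) at percentile 100. The type I interferon list had a median of 1.18 (1.03 to 1.39), with 15 of 16 higher, including Ifit1 at 19.3 and 103 CPM and Ifit3 at 20.3 and 94.9 CPM. The interferon gamma list had a median of 0.66 (0.51 to 0.91), with 8 of 15 higher, and MHC class I 0.43 (0.32 to 0.49). The chemokine receptor Ccr2 was 98.5 and 395 CPM, and Fyco1, Gbp9, AY036118 and Ifi206 had log2 ratios from 1.41 to 1.81. Exhaustion genes had a median of 0.08 (0.01 to 0.21). Of these Pdcd1 was 140 and 146 CPM, Havcr2 91.4 and 117 CPM, Ctla4 135 and 171 CPM, Cd160 113 and 57.8 CPM and Tnfrsf9 63.5 and 34.5 CPM. Lower genes included Tcf7, a transcription factor of memory and stem-like T cells, at 82.8 and 33.0 CPM. The chemokine Xcl1 was 931 and 425 CPM and the granzyme Gzmf 76.7 and 18.2 CPM, while Tbc1d4, Ccl1, Pkp4 and Cdca3 had log2 ratios from -1.62 to -1.19. Cell cycle genes had a median of -0.35 (-0.46 to -0.30), naive or memory genes -0.12 (-0.47 to 0.17) and dissociation stress genes 0.34 (0.29 to 0.47).

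The 4 CD8 T-like clusters were of nearly even size in the library labelled WT and uneven in the library labelled cKO. Cluster T3 held 60 and 736 cells, T7, led by Lag3 and Havcr2, 71 and 476, the cycling T14 56 and 172, and T16 60 and 46. T3 was led by Gzmk, Ifitm1 and Ccl5, so their log2 ratios of 2.56, 1.45 and 1.76 may in part restate cluster sizes. With clusters weighted as in the library labelled WT, Ifitm1 moved to 0.42 and Ccl5 to 0.85, whereas Gzmk did not move by over 1.5 times. Values of Ccr7, Dapl1, Cd200, Nrgn and Nrn1, which led T16 and had log2 ratios from -2.39 to -1.43, also in part restate cluster sizes. So do those of the cell cycle genes, which led T14. A cluster that is mostly of 1 library may be that library and not a cell type. In cells thinned to 3913 UMIs, Gzmb was found in 39.1% (32.2 to 46.3) and 85.8% (83.7 to 87.6), with 50 and 117 shallower cells left out. Unthinned shares of cells with Gzmb were 48.2% and 89.4%, at median depths of 5660 and 6912.5 UMIs. B-like cells thinned to 1897 UMIs had Gzmb in 1.39% and 2.58%. Markers of macrophages (-2.21) and of melanocytic cells (-2.72) were lower in CD8 T-like cells of the library labelled cKO. With clusters weighted as in the library labelled WT, the type I interferon median was 0.61, the exhaustion median 0.18 (0.00602 with every cell weighted equally, 0.03 in thinned cells) and 22 genes moved by over 1.5 times. Among these were Gzma from 2.03 to 0.94, Ccl5 to 0.85, Ccr2 from 1.99 to 1.17, Ifit1 from 2.36 to 1.5 and Ifit3 from 2.17 to 1.249, while Ccl1 (0.40), Nrn1 (0.11) and the cell cycle median (0.18) turned. Of the lower genes Tcf7 moved from -1.30 to -0.82, Tbc1d4 from -1.62 to -0.55, Pkp4 from -1.35 to -0.46, Cdca3 from -1.19 to -0.64, Xcl1 from -1.13 to -0.31, Cd160 from -0.96 to -0.26 and Tnfrsf9 from -0.86 to -0.18. Gzmf moved from -2.01 to -0.37 with every cell weighted equally and to -0.85 in thinned cells. Thinned cells also moved Pkp4 to -2.42, Tnfrsf9 to -1.46, Nrn1 to -2.71, Havcr2 from 0.35 to 0.18, Ctla4 from 0.33 to 0.13 and the cell cycle median to -0.72, and weighting every cell equally moved Nrn1 to -2.42 and the cell cycle median to -0.56. Under marker gates the medians were 1.70 for cytotoxic, 1.19 for exhaustion, 1.14 for interferon gamma, 0.74 for type I interferon and -0.07 for cell cycle genes, and Cd160 (0.57), Gzmf (0.17), Nrn1 (0.21), Tbc1d4 (0.16), Tnfrsf9 (0.36) and Xcl1 (0.77) turned. These gates moved 22 genes by over 1.5 times. Gzmb rose from 1.83 to 3.29, Gzma to 3.28, Havcr2 to 1.13 and Ctla4 to 1.04. Closer to no difference were Ifit1 (1.11), Ifit3 (1.41), Ccr7 (-0.43), Dapl1 (-0.55), Cd200 (-0.11) and Nrgn (-0.014).

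The interferon gamma response list was higher in the library labelled cKO in each of the 10 classes compared. Its median was 1.26 (1.03 to 1.55) in neutrophil-like, 0.77 (0.65 to 0.87) in cDC2-like, 0.67 (0.56 to 0.78) in other T, 0.64 (0.20 to 0.76) in B-like (0.28 after subtraction of myeloid RNA estimated from marker genes), 0.51 (0.42 to 0.64) in NK-like, 0.50 (0.42 to 0.64) in regulatory T-like and 0.45 (0.35 to 0.64) in CD4 T-like cells. The type I interferon list ran from 0.71 (0.48 to 0.84) in regulatory T-like to 1.14 (0.99 to 1.23) in cDC2-like cells among these classes, except for B-like cells, whose 0.25 (-0.01 to 0.64) had an interval reaching 0. In NK-like cells Gzmb was 388 CPM (371 to 406) and 1335 CPM (1311 to 1360) and Prf1 405 and 711 CPM. The NK-like clusters held 863 and 720 cells (T2), 269 and 174 (T10), 99 and 275 (T11), 16 and 129 (T15) and 27 and 13 (T19), T15 being led by interferon-induced genes such as Ifi44 and Mx1 and T11 by Prf1, Gzma and Gzmb, so these values in part restate cluster sizes. With clusters weighted as in the library labelled WT, the NK-like log2 ratios moved from 1.78 to 1.26 for Gzmb and from 0.81 to 0.51 for Prf1, and the type I interferon median from 0.82 to 0.48. Marker gates gave interferon gamma medians of 1.85 in B-like, 1.16 in regulatory T-like, 0.84 in NK-like and 0.77 in CD4 T-like cells, and type I interferon medians of 1.19 in B-like, 1.15 in regulatory T-like and 1.35 in neutrophil-like cells (0.46 there with every cell weighted equally). The B-like type I interferon median was 0.62 with doublets kept and 0.15 in thinned cells. In regulatory T-like cells Foxp3 was 456 CPM (425 to 489) and 416 CPM (390 to 443), and Ctla4 1075 and 939 CPM. RNA of other cells differed beside these lists, with macrophage markers at -2.22 in NK-like cells, C1qa there being 71.8 and 10.7 CPM. Pmel in NK-like cells was 28.2 and 2.47 CPM, and Hbb-bs in B-like cells was 18.5 and 4267 CPM, with a UMI in 2.22% and 6.57% of cells. Neutrophil-like cells had median depths of 1911.5 and 8152 UMIs, and NK markers in them had a median of 1.63, so their values rest on unlike cells.

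NK-like cells of the 2 libraries differed in the Klra genes, which encode Ly49 receptors for MHC class I and sit together on chromosome 6. These genes were singled out after their values were seen. Klra8, the activating receptor Ly49H, was 385 CPM (368 to 402) in the library labelled WT and 0.824 CPM (0.331 to 1.70) in the library labelled cKO. Klra4 was 564 CPM (544 to 585) and 24.8 CPM (21.6 to 28.4), and Klra6 had 58 and 0 UMIs. Klra9 was 179 and 45.3 CPM, whereas Klra3 was 66.0 and 299 CPM and Klra7 317 and 282 CPM. Rpl29, a ribosomal protein gene on chromosome 9, was lower in the library labelled cKO in all 10 compared classes, with log2 ratios from -3.17 to -2.72. Klra4 also led NK-like cluster T2, in which Klra8 had a log2 ratio of -8.06.

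**Figure D4:**
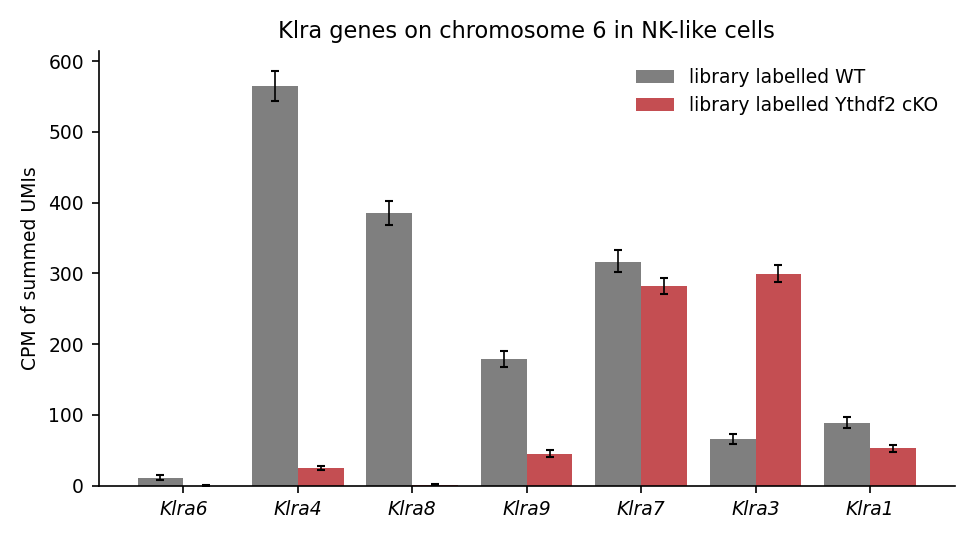
RNA of 7 Klra genes in NK-like cells as CPM of summed UMIs for the library labelled WT (grey) and the library labelled cKO (red), with exact 95% Poisson intervals for counting error. Klra8 stands at 385 and 0.824 CPM and Klra3 at 66.0 and 299 CPM.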

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

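All tests in this part were chosen after the results were seen, except those of a strain variant and of an NK subset. Clusters C9 and T4 got no name and were left out of the gene comparisons, and their shares were higher in the library labelled cKO. C9 carried markers of 2 lineages and made up 2.20% of the library labelled WT and 5.31% of the library labelled cKO. Cd3e UMIs were found in 85.5% and 89.6% of its cells and Csf1r UMIs in 84.7% and 93.8%, at median depths of 14270 and 24430 UMIs. T4, led by Sult2b1, Dhrs3 and Serpinb6b, made up 1.13% and 5.29%, with 124 and 481 cells. Cd3e UMIs were found in 2.31% of its cells, and it passed the rule for NK clusters. It stayed unnamed only because another marker set had more markers among its leading genes. Counted with T4, NK-like cells were 12.7% and 19.7%, so the NK-like gene comparisons may leave out NK cells.

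Ythdf2 RNA was higher in the myeloid classes of the library labelled cKO, against the label. RNA from other cells would have reached lymphoid droplets too, but the gain in NK-like cells was 0.0120 of that in monocyte-like cells. Recombination in Lyz2-expressing cells that leaves the counted part of the RNA would confine a difference to classes with Lyz2. By itself it would not make Ythdf2 RNA higher. In the compared classes, the lowest ratio among the 4 with at least 1000 CPM of Lyz2 was 2.44 and the highest among the 6 others was 1.26. This explanation stays open, also because 2 classes too small to be compared had high ratios at low Lyz2. These were mature DC-like cells with 2.02 at 146 CPM and melanocytic cells with 2.39 (1.999 to 2.84) at 131 CPM. The melanocytic class held 167 and 22 cells, and C1qa in it was 48.7 and 151 CPM. RNA of macrophages could thus account for part of the melanocytic value, which was not tested. In mature DC-like cells, 75 and 73 in number, C1qa was lower, at 61.9 and 27.7 CPM. Cd3e UMIs were found in 2.67% and 35.6% of the mature DC-like cells, so they also carried T cell RNA. Swapped labels and correct labels cannot be told apart, since the Lyz2 ratio of 0.475 in monocyte-like cells would speak against a swap only if the driver sits at Lyz2, which the labels do not say.

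The interferon gamma response list was higher in the library labelled cKO in 10 of 10 compared classes. Myeloid RNA in lymphoid droplets was estimated from 12 or 13 macrophage and monocyte markers and subtracted, a gene choice that replaced an earlier one after its result was seen, and NK-like cells had a median of 0.455, with 0.28 to 0.66 over 6 lymphoid classes. B-like cells had the lowest of these, and their type I interferon median went from 0.25 to about 0, so free RNA could account for that part. The higher list was not confined to cells whose Ythdf2 RNA differs. In NK-like cells, whose Ythdf2 was alike, the list median had a lower bound of 0.418. Whether an effect of the genotype was confined to cells whose Ythdf2 RNA differs cannot be told. A difference between the tumours of the 2 libraries could also raise the list in NK-like cells. With 1 library each, the genotype cannot be told apart from a difference between the tumours, mice or preparations of the 2 libraries. The genotype thus stays an untested explanation.

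Klra4, Klra6 and Klra8 were lower in NK-like cells and Rpl29 was lower in every compared class of the library labelled cKO. The Klra sum had a ratio of 0.446, which leaves reads shared between paralogs open, since reads that match several genes are not counted. The Klra8 log2 ratio within cluster T2 was -8.06, past the value written beforehand as arguing against fewer cells of an NK subset. It argues against a change in cluster sizes alone. Loss of Klra8-bearing cells inside T2 would give the same value, so fewer cells of such a subset stays open. For a strain variant, genes within 10 Mb were counted, with Klr genes and Eps8 left out as written beforehand. Of those left out, Klre1 had log2 ratios from -1.04 to -0.67 in the 3 classes measured, and Eps8 also sits on chromosome 6. Klrk1 (36.6 and 122 CPM), Klra2 (187 and 116 CPM) and Eps8 (188 and 49.1 CPM) were named by the size rule in monocyte-like cells. Genes of these names were left out, so the count does not weigh them. Of the 75 genes counted near Klra8, 4% (0.833 to 11.3), namely Cdca3, Lockd and Usp18, differed the same way in every class measured. Elsewhere it was 0.540%, which met the value written beforehand, while 0 of 86 (0 to 4.199%) did near Rpl29. Usp18 is an interferon gene, so the requirement was made stricter after this was seen. Without list genes the share near Klra8 was 2 of 68 genes, 2.94% (0.358 to 10.2). A strain variant and other differences between the mice of the 2 libraries thus cannot be told apart.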

How the results depend on the processing

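Alternatives named as added were chosen after the data were seen, as were the results followed outside macrophage-like and CD8 T-like cells. No paired analysis was possible because each group holds 1 library. Of 80 alternatives over 12 shares, 62 stayed within the interval, 17 moved in size and 1 reversed. For 38 list medians it was 234, 75 and 2 of 311, and for 106 named genes 507, 289 and 10 of 806. Marker gates were defined for 7 classes and gave no value for others, and the filter on low values does not act on single genes. Values below are log2 ratios, and the cause was not tested unless given. Depth limits rare genes in B-like and neutrophil-like cells of the library labelled WT, with median depths of 2244.5 and 1911.5 UMIs.

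For shares, the macrophage-like value of -3.31 became -2.58 at resolution 2.0, -1.36 under marker gates and -2.43 with cluster C11 counted in (added; more cells by construction). The monocyte-like value of 0.60 became 0.34 with at most 5% mitochondrial UMIs and -0.0048 at resolution 2.0, where the shares were 15.4% and 15.3%, so no difference was left. The CD8 T-like value of 2.81 became 2.49 at resolution 2.0 and 1.15 under marker gates. The NK-like value of 0.32 became 0.60 with at least 500 genes, 0.56 with at most 5% mitochondrial UMIs, 0.71 with doublets kept, 0.58 and 0.63 at resolutions 0.5 and 2.0, 0.53 under marker gates and 0.63 with cluster T4 counted in (added).

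Under marker gates, CD8 T-like medians became 1.19 for exhaustion (from 0.08), 1.70 for cytotoxic (0.74), 1.14 for interferon gamma (0.66) and 0.74 for type I interferon genes (1.18), and Ythdf2 1.01 (0.17). Cd160 (0.57), Gzmf (0.17), Nrn1 (0.21), Tbc1d4 (0.16), Tnfrsf9 (0.36) and Xcl1 (0.77) turned from negative. Macrophage-like medians became 0.91 for MHC class I, 1.5 for MHC class II, 0.35 for alternatively activated, 1.24 for inflammatory, 1.86 for interferon gamma and 1.70 for type I interferon genes, with Ythdf2 at 2.54 (2.32) and Arg1 turned to -0.039.

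In thinned cells, Ythdf2 in CD8 T-like cells became 0.60, and macrophage-like medians 1.15 for MHC class II, 1.10 for inflammatory and 0.82 for type I interferon genes. With every cell weighted equally, CD8 T-like exhaustion became 0.00602 and cytotoxic genes 0.68, macrophage-like MHC class I 0.40, inflammatory genes 0.73 and Ythdf2 2.21. With doublets kept, CD8 T-like type I interferon became 1.43, macrophage-like MHC class II 1.09 and interferon gamma 1.10. At least 500 genes per cell gave 1.09 for MHC class II and 0.34 for inflammatory genes in macrophage-like cells and, added, -0.0552 for alternatively activated and 0.82 for type I interferon genes in monocyte-like cells. A pseudocount of 10 CPM, which shrinks ratios by construction, gave 0.88 for CD8 T-like type I interferon, 0.48, 0.97 and 0.83 for macrophage-like inflammatory, interferon gamma and type I interferon genes, 2.20 for Ythdf2 there and, added for monocyte-like cells, 0.97 for interferon gamma and 2.77 for Ythdf2. Median-of-ratios factors gave 0.93 for monocyte-like type I interferon (added).

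With clusters weighted as in the library labelled WT (added; this removes differences in cluster sizes by construction), CD8 T-like type I interferon became 0.61, and Ccl1 (0.40), Nrn1 (0.11) and the cell cycle median (0.18, from -0.35) turned. Macrophage-like inflammatory genes became 0.30, and the alternatively activated list (-0.16) and Arg1 (-0.16) turned.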

Other observations

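All values of this part were picked after the data were seen. Regulatory T-like cells, which restrain other T cells through genes such as Foxp3 and Ctla4, had a function list median of -0.13 (-0.21 to -0.07), with 0 of 13 members past 1.5-fold. Gzmb in these cells was 713 CPM in the library labelled WT and 1088 CPM in the library labelled cKO. It was higher in all 9 classes in which it was measured, with log2 ratios from 0.61 to 4.36. Cd8a in regulatory T-like cells was 22.95 and 73.97 CPM. RNA of CD8 T cells could thus account for part of the Gzmb difference there, which was not tested. cDC2-like cells, which present antigen to CD4 T cells, had a DC maturation median of 0.40 (0.30 to 0.55) in the library labelled cKO, with 3 of 8 genes higher and 1 lower, while MHC class II stood at 0.08. Gzma in cDC2-like cells was 12.3 and 105 CPM, a gene of T and NK cells.

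Before doublets were removed, Foxp3 was found in 33.0% (1617 droplets) and 36.5% (982) of droplets with at least 2 UMIs each of Cd3 genes and Csf1r, at median depths of 24550 and 25750 UMIs. In droplets with T cell RNA alone it was found in 10.6% (2259) and 8.84% (2852), at median depths of 3582 and 6656 UMIs. Cd8a was found in 33.0% and 51.5% of the first droplets and in 18.9% and 51.75% of the second, and none of these shares was thinned to 1 depth. Cluster C9 had Foxp3 in 61.6% and 51.2% of cells. Hbb-bs, a haemoglobin gene of red cells, was 18.5 and 4267 CPM in B-like cells and 1761 and 19.7 CPM in neutrophil-like cells, with a UMI in 6.57% of B-like cells of the library labelled cKO and 9.47% of neutrophil-like cells of the library labelled WT, so few cells carried these values. Eps8 had log2 ratios of -1.92 in monocyte-like, -1.50 in neutrophil-like and -1.24 in cDC2-like cells, against 0.24 in B-like cells.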
